A study of Mus musculus with 26 samples.

How the data were processed

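RNA of macrophages sorted from pooled pancreatic islets of female NOD/ShiLtJ and C57BL/6J mice had been amplified and sequenced, and 26 libraries in 7 groups of strain and age were used (15 NOD, 11 B6). Grouping came from the labels. The labels name no batch and do not state that replicate numbers pair libraries, so libraries were treated as independent within groups.

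The values used were whole read counts per gene, as deposited by the authors. Per the submitters' processing notes, STAR, HTSeq and DESeq2 were used with the builds mm10 and GRCm38, with versions not given in the sources used here. They were taken as not normalized. The table held 41092 lines, of which 534 were repeats of 286 gene IDs and were removed, leaving 40558 genes. Symbols and coordinates came from GENCODE M21 (GRCm38) for 40254 of them. Reads of NOD mice are set against a reference built from C57BL/6J, and strain variants were not corrected for. Several members of the fixed lists (H2-Ea, Gbp5, Gbp6, Ighd and Ahsp) were not analysed here.

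Total counts per library ran from 4957125 to 13859955, and 14152 to 26491 genes had a count. A gene with 0 counts in a library was taken to lie below 3 counts there, which is 0.216 to 0.605 CPM. Where a group had 0 counts, a fold change is given as a minimum against 3 counts over that group, and where it had 1 to 3 counts as a ratio with a 95% counting interval. A list's median was also computed with such members at their bound. Of 128 called list comparisons, 9 medians changed, by at most 0.22, and 0 changed sign.

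Analyses ran in R 4.3.3. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), leaving 19703, and scaled by TMM in edgeR 4.0.16. One quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 26 libraries. It gave 13 comparisons: NOD against B6 at 2, 4 and 12 weeks, 4 changes with age in NOD, 3 in B6, and 3 strain-by-age interactions. A gene was called at an adjusted p (Benjamini-Hochberg over all genes tested) under 0.05. The SE of a log2 fold change is its size divided by the square root of the test's F value.

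Gene lists were fixed before the data were examined: 15 of macrophage genes and programs and 11 of other cells that islets or the sort gate could hold. The first were type I interferon-stimulated, interferon-gamma response, MHC class II and class I presentation, inflammatory cytokine and chemokine, alternatively activated or perivascular, core macrophage, lipid-associated and phagocytic, complement, cell cycle, growth factor and matrix remodelling, immediate early and dissociation stress, glycolysis, oxidative phosphorylation and cholesterol biosynthesis genes. The others marked islet endocrine, acinar, duct, T, B and plasma, dendritic, natural killer, erythroid, endothelial and stromal cells, monocytes and neutrophils. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 26 lists within a comparison. Alternatives were an inter-gene correlation estimated per list and the rotation test fry. Members were also counted after adjustment over their list alone.

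The rule for naming genes was also fixed before the data were examined. It takes the 8 largest rises and falls of each strain comparison and of 2 to 12 weeks in each strain, and the 5 largest of the other comparisons. These had to pass the threshold, reach a mean of 5 CPM in the higher group and, except for interactions, separate all libraries of the 2 groups. Gene models without a descriptive symbol were skipped. The rule adds the 10 genes with the largest minimum change among those called at all 3 ages, up to 4 members of each list by smallest adjusted p, and the check genes Ins1, Ins2, Prss2, Cd3e, Cd79a, Nnt, Xist, Ddx3y, Kdm5d, Eif2s3y and Uty. Some genes were left out for room, and genes with near-identical copies are named as uncertain.

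Simulated counts were drawn at the depths of the same libraries, with 1 spread per gene shared by all groups. On these counts the test was checked with 50 genes changed per fold size. For folds of 2, 4, 8 and 16 it recovered 6, 24, 38 and 42 of 50 in NOD against B6 at 12 weeks, and 7, 28, 39 and 44 in NOD 12 against 2 weeks. In B6 12 against 2 weeks it recovered 7, 24, 37 and 43, and in NOD against B6 at 4 weeks 8, 24, 43 and 43. The median ratio of estimated to true log2 fold lay between 0.94 and 1.11. Among unchanged genes 1 to 3 were called per comparison, and camera with the preset correlation gave an unchanged list p = 0.0221 in NOD against B6 at 12 weeks and 0.562 to 0.797 in the others.

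Alternatives tried were RLE and upper-quartile scaling, no filter, a stricter filter (5 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, a fit of the compared groups alone, a covariate of islet endocrine and acinar levels, a minimum absolute log2 fold change of 1, and the omission of each library. A fit without the B6 4 week libraries was added after the data were seen. Other splits of the libraries into groups of the same sizes were fitted in the same way.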

Results

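Macrophages were sorted from the pancreatic islets of female mice of 2 inbred strains and their RNA was sequenced as whole populations. NOD/ShiLtJ (NOD) mice develop autoimmune diabetes spontaneously, and C57BL/6J (B6) mice do not. The 26 libraries fell into 7 groups: NOD at 2, 4 and 8 weeks of age (n = 4 each) and at 12 weeks (n = 3), and B6 at 2 weeks (n = 3) and at 4 and 12 weeks (n = 4 each). The sort kept live CD45+ F4/80+ CD11c+ cells without B220 or CD90, so the levels of Ptprc, Adgre1 and Itgax were set in part by the gate and are not treated as findings. Total counts per library ran from 4.96e+06 to 1.386e+07. Group means were 1.22e+07, 1.21e+07, 1.21e+07 and 9.06e+06 in NOD at 2, 4, 8 and 12 weeks and 8.23e+06, 1.07e+07 and 6.68e+06 in B6 at 2, 4 and 12 weeks. Of 40558 genes measured, 19703 passed the expression filter and were tested. The B6 4 week libraries each held fewer genes with a count (14152 to 17839) than any other library. Their mean Spearman correlation with each other across genes was 0.727, against 0.835 to 0.85 in the other B6 groups and 0.915 to 0.95 in NOD, where genes are not independent replicates. Gene levels are counts per 1e+06 counts of the TMM-scaled library (CPM, mean ± SD over libraries), and log2 fold changes carry ± SE. Adjusted p-values come from the edgeR quasi-likelihood test for genes and from camera (limma) for gene lists. Members of a list were counted as higher or lower when they passed adjustment over all genes. Each library was a pool of islet cells from several mice, but the labels do not otherwise state that replicates had separate origins. The p-values therefore measure the spread between these libraries, while counting intervals and floors cover counting error alone.

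The X-linked transcript Xist, expressed from the inactive X chromosome of females, had 9645 to 39919 counts in every library, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had at most 8. Nnt, part of which is deleted in C57BL/6J, was higher in NOD at 4 weeks (log2 fold change 1.03, adjusted p = 0.0479), with overlapping libraries. This call was lost with DESeq2, RLE scaling, the stricter filter, a covariate of islet endocrine and acinar levels (islet covariate), a fit of these groups alone (adjusted p = 0.0551 to 0.427) and most single omissions. Its differences at 2 weeks (1.02, adjusted p = 0.193) and 12 weeks (0.51, adjusted p = 0.723) did not pass, and reads over the deleted exons were not counted separately here.

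In islet macrophages of 2-week-old mice, the sialyltransferase gene St6galnac2 stood at 293 ± 51 CPM in NOD (n = 4) and 2.49 ± 0.495 CPM in B6 (n = 3), 117-fold higher in NOD (log2 fold change 6.87 ± 0.98, adjusted p = 0.000153). Its relative St6galnac1 reached 12.3 ± 4.61 CPM in NOD and had 0 counts in B6, at least 107-fold higher when B6 is set at 3 counts over the group (adjusted p = 4.62e-05). Ccn1, which encodes a secreted matrix-associated protein, was 154-fold lower in NOD (2.5 ± 2.4 against 376 ± 141 CPM, adjusted p = 2.84e-07). Spint1, a membrane inhibitor of serine proteases, was 107-fold lower (0.962 ± 0.952 against 103 ± 17.8 CPM, adjusted p = 2.96e-09). The muscarinic receptor gene Chrm3 was higher in NOD (24.9 ± 9.79 CPM, log2 fold change 4.62 ± 0.86, adjusted p = 0.00109). Among genes with near-identical copies, whose levels are uncertain, Ifi202b was 128-fold higher (25.3 ± 4.21 against 0.185 ± 0.0615 CPM, adjusted p = 5.10e-09). In the same class, Trim12a (209-fold, adjusted p = 4.97e-07), Ifi206 (log2 fold change -6.14 ± 0.80) and H2-Q5 (-6.68) were lower. With few counts in the lower group, Zfp979 was higher in NOD by a ratio of 164 (95% counting interval 45.4 to 1360). Stac, an adaptor of calcium channels, was lower by a ratio of 345 (62.0 to 13600). In total 421 genes differed, 177 higher and 244 lower in NOD (148 and 338 with RLE, 140 and 442 with upper-quartile scaling), and 3153 had an unadjusted p under 0.05.

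Of 26 type I interferon-stimulated genes at 2 weeks, 11 were lower in NOD, 0 were higher and 15 did not pass, with a median log2 fold change of -1.37 (camera adjusted p = 8.94e-14, and 15 lower when adjusted over the list alone). Lower members included Oasl2, an antiviral oligoadenylate synthetase relative (47.6 ± 15.0 against 208 ± 119 CPM, -2.13 ± 0.27, adjusted p = 4.60e-06), and the nucleic acid sensor Zbp1 (-2.29 ± 0.42, adjusted p = 0.001). Among 12 MHC class II presentation genes, 4 were lower and 8 did not pass (median -0.44, adjusted p = 0.000109, adjusted p = 0.214 with an estimated correlation, 5 lower over the list alone). The invariant chain gene Cd74 stood at 3390 ± 490 CPM in NOD and 8460 ± 2170 in B6 (-1.32 ± 0.15, adjusted p = 3.40e-07). H2-Ab1, the class II beta chain, was lower by the same log2 fold change (1330 ± 199 against 3340 ± 1340 CPM, adjusted p = 5.09e-06). Interferon-gamma response genes had 5 of 23 lower and 0 higher (median -1.44, adjusted p = 0.000614, adjusted p = 0.329 with an estimated correlation, 1 higher and 9 lower over the list alone). The Fc receptor gene Fcgr4 (-1.66 ± 0.27) and the GTPase gene Irgm2 (-2.40 ± 0.41) were among them. MHC class I presentation had 3 of 14 lower, H2-K1 (-0.98 ± 0.16) and B2m (-0.92 ± 0.17) included (median -0.60, adjusted p = 0.00312, adjusted p = 0.329 with an estimated correlation). Without B6 2 week replicate 2 neither the interferon-gamma response list (adjusted p = 0.535) nor the MHC class I list (adjusted p = 0.391) was called.

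Immediate early and dissociation genes were lower in NOD at 2 weeks in 7 of 21 members, with 0 higher (median -0.98, adjusted p = 5.75e-13, adjusted p = 0.214 with an estimated correlation, 15 lower over the list alone). The transcription factor gene Junb (-1.42 ± 0.23) and the chaperone gene Hspa8 (-1.25 ± 0.20) were lower. Oxidative phosphorylation genes were higher in 3 of 30 members and lower in 0 (median 0.68, adjusted p = 7.33e-09, adjusted p = 0.0601 with an estimated correlation). The ATP synthase genes Atp5o (1.55 ± 0.36, adjusted p = 0.0129) and Atp5a1 (0.78) were higher. Lipid-associated and phagocytic genes had 3 higher and 1 lower of 23 (median 0.19, adjusted p = 0.00189, adjusted p = 0.329 with an estimated correlation), led by the lipid receptor gene Trem2 (1.54 ± 0.25, adjusted p = 0.000191). Outside the lists just named, the chemokine gene Cxcl14 stood at 297 ± 23.4 CPM in NOD and 15.7 ± 3.25 in B6 (4.24 ± 0.37, adjusted p = 2.96e-09). The monocyte chemokine receptor gene Ccr2 stood at 47.1 ± 17.8 and 6.49 ± 1.83 CPM (2.86 ± 0.40, adjusted p = 1.93e-05). The Fc receptor subunit gene Fcer1g was lower (-1.55 ± 0.14, adjusted p = 6.35e-09). A fit of these 2 groups alone called 906 genes, voom 1021, DESeq2 1147, and a fit without the B6 4 week libraries 1880. Of the genes named, Cd74 lost its call with voom (adjusted p = 0.128), and Zbp1, Atp5o and Atp5a1 did in single omissions. Without single libraries the count was 280 (NOD 2 week replicate 2 left out), 250 (B6 2 week replicate 1) and 239 (B6 2 week replicate 2).

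By 4 weeks (n = 4 per strain), NOD macrophages held 3420 ± 469 CPM of H2-Ab1 against 11300 ± 2130 in B6 (-1.72 ± 0.16, adjusted p = 8.39e-09). Cd74 stood at 7670 ± 160 CPM against 30500 ± 7270 (-1.99 ± 0.14, adjusted p = 3.35e-11). Ccn1 was 192-fold lower in NOD (4.11 ± 3.57 against 792 ± 349 CPM, adjusted p = 6.52e-08). Apoe, the lipid carrier, stood at 4390 ± 295 CPM in NOD and 14900 ± 3630 in B6 (-1.77 ± 0.15, adjusted p = 5.80e-10). Colec12, a scavenger receptor gene, had 0 counts in B6 and 21.2 ± 3.57 CPM in NOD, at least 249-fold higher. The chemokine receptor gene Ccr6 (25.1 ± 1.95 CPM in NOD) was higher by a ratio of 880 (158 to 34800). Lower in NOD were the villin relative Vill (30.0 ± 19.0 CPM in B6, -8.06 ± 1.13, adjusted p = 8.64e-06) and the G-protein regulator Rgs6 (29.7 ± 19.9 CPM in B6, -7.30 ± 1.27, adjusted p = 0.000186). The developmental gene Mab21l1 had 0 counts in NOD (at least 153-fold lower). The interleukin-1 receptor antagonist gene Il1rn was higher (72.1 ± 10.6 against 6.41 CPM, 3.47 ± 0.53, adjusted p = 4.42e-05). In all 3450 genes differed, 1710 higher and 1740 lower, but 1816 and 1519 with upper-quartile scaling.

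Of the MHC class II presentation genes at 4 weeks, 9 were lower, 1 higher and 2 did not pass (median -0.85, adjusted p = 1.70e-07, adjusted p = 0.188 with an estimated correlation). Immediate early and dissociation genes were lower in 18 of 21 members (median -1.43, adjusted p = 3.72e-18, adjusted p = 0.188 with an estimated correlation, 19 over the list alone). Examples were the mRNA decay factor gene Zfp36 (2770 ± 536 against 8430 ± 1060 CPM, -1.61 ± 0.21, adjusted p = 2.40e-06) and Hspa8 (-1.53 ± 0.19). Core macrophage identity genes, which hold the sort markers, had 7 lower and 2 higher of 18 (median -0.32, adjusted p = 0.00122, adjusted p = 0.207 with an estimated correlation). Oxidative phosphorylation had 9 members higher and 1 lower (median 0.96, adjusted p = 7.80e-05, adjusted p = 0.22 with an estimated correlation, 13 higher over the list alone). The cytochrome oxidase subunit Cox6c (2.71 ± 0.54) and the complex I subunit Ndufb8 (1.75) were among them. Cell cycle genes had 5 higher and 1 lower of 32 (median 0.74, adjusted p = 7.80e-05, adjusted p = 0.238 with an estimated correlation), including the topoisomerase gene Top2a (2.30 ± 0.45). Islet endocrine cell genes had 4 of 17 higher and 0 lower (median 1.09, adjusted p = 0.013, adjusted p = 0.429 with an estimated correlation). Ins2, an insulin gene, stood at 2800 ± 1850 CPM in NOD and 720 ± 200 in B6 (1.96 ± 0.47, adjusted p = 0.00784). Type I interferon-stimulated genes had 5 lower (median -0.70, adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation). MHC class I presentation had 5 lower and 1 higher (median -0.47, adjusted p = 0.0221, adjusted p = 0.44 with an estimated correlation). Inflammatory cytokines and chemokines had 9 lower and 2 higher of 25, with a median of -0.51, or -0.53 with genes lacking counts in 1 group set at their bound (adjusted p = 0.0234, adjusted p = 0.606 with an estimated correlation). Glycolysis had 4 lower and 1 higher of 17 (median -0.50, adjusted p = 0.0409, adjusted p = 0.44 with an estimated correlation), and cholesterol biosynthesis 4 higher and 2 lower of 19 (median 0.67, adjusted p = 0.026, adjusted p = 0.299 with an estimated correlation). A fit of these 2 groups alone called 742 genes, 741 of them among the 3450, and voom called 706. Cox6c and Ndufb8 lost their call in the groups alone, Il1rn, Mab21l1, Top2a and Ins2 with voom, and Ins2 with the islet covariate.

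At 12 weeks (NOD n = 3, B6 n = 4) the largest differences that passed included chemokine genes. Cxcl13, a B cell attractant, stood at 1570 ± 707 CPM in NOD and 5.51 ± 2.29 in B6 (280-fold, log2 fold change 8.13 ± 0.39, adjusted p = 2.59e-15). Ccl8, another chemokine gene, was 401-fold higher (178 ± 47.8 against 0.454 ± 0.208 CPM, adjusted p = 5.96e-10). Cxcl9, an interferon-gamma-induced attractant of T cells, was 90.1-fold higher (2700 ± 628 against 29.9 ± 12.7 CPM, adjusted p = 0.00019). C3, the central complement component, reached 1410 ± 211 CPM against 19.7 ± 6.20 (6.16 ± 0.44, adjusted p = 1.56e-10). The interferon-inducible GTPase gene Iigp1 (61.8 ± 22.1 CPM in NOD, 6.71 ± 1.04, adjusted p = 5.29e-05) was also higher. Serpina3g, of a family of close copies and thus uncertain, was higher too (134 ± 7.10 against 1.14 CPM, 6.89 ± 0.90, adjusted p = 3.24e-06). The fatty acid receptor gene Cd36 was lower in NOD (6.66 ± 1.55 against 114 ± 30.5 CPM, -4.09 ± 0.32, adjusted p = 2.73e-10), as was the elastase gene Mmp12 (148 ± 20.0 against 855 ± 185 CPM, -2.53 ± 0.24, adjusted p = 7.97e-09). Apoe (-1.88 ± 0.17, adjusted p = 1.54e-09) and the adhesion gene Hepacam2 (34.8-fold, adjusted p = 0.00019) were lower as well. So was Siglech, a lectin of plasmacytoid dendritic cells and some macrophages (21 ± 9.2 against 140 ± 38.1 CPM, -2.74 ± 0.34, adjusted p = 1.18e-06). The high-affinity Fc receptor gene Fcgr1 was higher (767 ± 166 against 128 ± 30.0 CPM, 2.58 ± 0.17, adjusted p = 9.29e-12). In total 875 genes differed, 468 higher and 407 lower. More were lower than higher with RLE (444 higher, 498 lower), upper-quartile scaling (385, 549) and DESeq2 (669, 749).

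Interferon-gamma response genes were higher in NOD at 12 weeks in 10 of 23 members, with 0 lower and 13 not passing (median 1.84, adjusted p = 3.25e-16, 14 higher over the list alone). Members included the chemokine gene Cxcl10 (160 ± 41.8 against 24.2 CPM, 2.73 ± 0.40, adjusted p = 1.93e-05) and the guanylate-binding protein gene Gbp7 (2.43 ± 0.33). MHC class I presentation had 10 of 14 higher (median 1.15, adjusted p = 3.68e-16), with H2-K1 (1250 ± 183 against 532 CPM, 1.23 ± 0.16, adjusted p = 4.24e-06) and the immunoproteasome subunit Psmb8 (1.82 ± 0.27) as examples. MHC class II presentation had 5 of 12 higher (median 0.52, adjusted p = 2.23e-05, adjusted p = 0.0997 with an estimated correlation), such as the peptide loading gene H2-DMb2 (3.30 ± 0.65). Complement genes had 6 higher and 1 lower of 14 (median 1.03, adjusted p = 3.89e-09), with C1qc up by 1.21 ± 0.12. Type I interferon-stimulated genes leaned the other way, with 1 higher, 1 lower and 24 not passing (median -0.48, adjusted p = 0.0146, adjusted p = 0.367 with an estimated correlation). Oxidative phosphorylation had 9 of 30 higher (median 1.15, adjusted p = 9.36e-12), the succinate dehydrogenase subunit Sdhc (1.99 ± 0.35) among them. Cholesterol biosynthesis had 2 of 19 higher (median 1.01, adjusted p = 1.47e-05), Dhcr7 (1.71) among them. Cell cycle genes had 6 of 32 higher (median 1.07, adjusted p = 2.92e-09), with Mki67 at 281 ± 49.6 against 101 ± 32.9 CPM.

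Immediate early and dissociation genes at 12 weeks had 4 lower and 1 higher (median -0.81, adjusted p = 5.09e-07, adjusted p = 0.266 with an estimated correlation), with Hspa8 lower again (-1.34 ± 0.21). In B6 12 week replicate 4 the mean log2 CPM of this list was 7.874, apart from the other B6 libraries (9.116 to 9.268) and below those of NOD. Inflammatory cytokines and chemokines had 6 higher and 1 lower of 25 (median 0.47, adjusted p = 0.000741, adjusted p = 0.303 with an estimated correlation). Among them were Il1rn (313 ± 108 against 14.6 CPM, 4.42 ± 0.56) and the prostaglandin synthase gene Ptgs2 (274 ± 123 against 42.6 CPM, 2.69 ± 0.39). Glycolysis had 4 of 17 higher (median 0.59, adjusted p = 0.00267, adjusted p = 0.158 with an estimated correlation). Genes of other cells moved too. Islet endocrine genes were higher in 4 of 17 (median 1.47, adjusted p = 5.09e-07). Ins2 stood at 2020 ± 521 against 321 ± 90.3 CPM (2.66 ± 0.50, adjusted p = 0.00217) and Ins1 at 653 ± 196 against 99.0 ± 35.4 CPM (2.72 ± 0.51, adjusted p = 0.00175). Monocyte genes were higher in 2 of 12 (median 2.30, adjusted p = 0.00622) and T cell genes in 1 of 14 (median 1.44, adjusted p = 0.0119, adjusted p = 0.0998 with an estimated correlation). Pancreatic acinar genes had 0 of 15 members passing (median 1.34, adjusted p = 0.0679), and Prss2, a trypsinogen gene, stood at 1.12 ± 0.504 and 0.285 ± 0.349 CPM. A fit of the 2 groups alone called 1651 genes, voom 1969, DESeq2 1418, a fit without the B6 4 week libraries 2211 and a fit with the islet covariate 392. Leaving out NOD 12 week replicate 3 left 529 genes. Ins2 lost its call with voom, H2-DMb2 with DESeq2, and Ins1, Ins2 and Dhcr7 with the islet covariate.

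Across the 3 ages, 72 genes were higher and 92 lower in NOD each time, 164 together, where 0.365 and 0.445 would be shared if calls at each age were independent. By contrast, 79 genes were called in opposite directions at any 2 ages. Spint1 (chromosome 2, 119237362 to 119249527) was lower by log2 -6.74 ± 0.59, -6.64 ± 0.57 and -5.32 ± 0.62 at 2, 4 and 12 weeks, and Ccn1 (chromosome 3, 145646976 to 145649981) by -7.27 ± 0.68, -7.59 ± 0.68 and -4.88 ± 0.70. Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962), was lower by -5.57, -4.62 and -4.62. Pianp, a paired-receptor ligand gene (chromosome 6, 124996694 to 125003096), was higher by 4.27 ± 0.62, 4.81 ± 0.57 and 4.34 ± 0.57, with 128 ± 15.8, 148 ± 28.6 and 128 ± 11.3 CPM in NOD. Of the genes with close copies, Trim12a (chromosome 7, 104299894 to 104315466) was lower by -7.71 ± 0.88, -7.04 ± 0.83 and -7.28 ± 0.96. Ifi202b (chromosome 1, 173962568 to 173982744) was higher by 7.00 ± 0.63, 7.32 ± 0.56 and 5.45 ± 0.51. Its neighbours Ifi213 (-5.87, -6.18 and -4.91) and Ifi206 (-6.14, -5.32 and -4.86) were lower. Coordinates are of GRCm38 (mm10). The shared count was 287 with DESeq2 and 100 with the islet covariate.

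Between 2 and 4 weeks of age in NOD (n = 4 each), Sparc, which encodes a matricellular glycoprotein, fell from 408 ± 33.4 to 46.9 ± 14.1 CPM (8.70-fold, log2 fold change -3.12 ± 0.36, adjusted p = 1.31e-05). The mannose receptor gene Mrc1 fell from 159 ± 22.6 to 55.0 ± 13.4 CPM (-1.53 ± 0.24, adjusted p = 0.00137). Rising genes included the interleukin-2 receptor chain gene Il2ra (17.0 ± 7.88 to 69.2 ± 16.8 CPM, 2.03 ± 0.28, adjusted p = 0.000209), the lymphocyte receptor gene Slamf7 (2.37 ± 0.39, adjusted p = 0.00236) and C3 (30.2 ± 7.55 to 103 ± 48.3 CPM, 1.76 ± 0.35, adjusted p = 0.0342). In the fit of all libraries 27 genes were called, 22 up and 5 down. Of 12 MHC class II presentation genes 4 rose and 8 did not pass (median 0.42, adjusted p = 2.20e-17). Rises were in H2-Ab1 (1330 ± 199 to 3420 ± 469 CPM, 1.36 ± 0.16, adjusted p = 1.31e-05), Cd74 (1.18 ± 0.14, adjusted p = 1.31e-05) and their transactivator Ciita (48.5 to 123 ± 24.7 CPM, 1.34 ± 0.23, adjusted p = 0.00323). Type I interferon-stimulated genes moved up together without a single member passing (median 0.74, adjusted p = 5.92e-15), as did MHC class I presentation genes (median 0.51, adjusted p = 4.39e-10, 6 up over the list alone). Interferon-gamma response genes had 1 member up (median 0.47, adjusted p = 3.83e-06, adjusted p = 0.0939 with an estimated correlation). Cxcl9 itself stood at 7.55 ± 5.53 and 95 ± 69.5 CPM without passing (adjusted p = 0.137). Growth factors and matrix remodelling genes had 1 of 20 up (median 0.40, adjusted p = 0.000862, adjusted p = 0.0556 with an estimated correlation). Islet endocrine genes shifted up with 0 passing (median 0.84, adjusted p = 3.83e-06, adjusted p = 0.065 with an estimated correlation). Fitting these groups alone called 128 genes, voom 173, DESeq2 105 and a fit without the B6 4 week libraries 114. The count was 17 without NOD 2 week replicate 2 and 16 without NOD 4 week replicate 3. C3 lost its call with no filter and in most single omissions, C3, Slamf7 and Cd74 with voom, and Slamf7 in the groups alone.

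From 4 to 8 weeks in NOD (n = 4 each), Cxcl13 rose from 3.94 ± 1.12 to 168 ± 40.9 CPM (42.5-fold, 5.41 ± 0.34, adjusted p = 6.56e-12). Ccl8 rose from 0.739 to 43.9 ± 13.5 CPM (58.1-fold, 5.86 ± 0.61, adjusted p = 6.37e-07) and C3 from 103 to 1210 ± 240 CPM (3.56 ± 0.38, adjusted p = 1.62e-06). Acod1, the enzyme gene for itaconate synthesis, rose 22.1-fold (2.39 ± 1.93 to 53.1 ± 17.6 CPM, 4.47 ± 0.73, adjusted p = 0.000539). Iigp1 rose by 5.39 ± 0.95 (adjusted p = 0.00136) and the interleukin-12 subunit gene Il12b by 4.27 ± 0.87 (adjusted p = 0.00658). Igf1, the insulin-like growth factor gene, fell 5.93-fold (47.5 ± 23.3 to 8.00 ± 2.04 CPM, adjusted p = 0.0397). Tjp1, of tight junctions (-2.91 ± 0.53, adjusted p = 0.00221), and Cd36 (50.1 to 14.7 CPM, -1.77 ± 0.26, adjusted p = 0.000104) fell as well. In total 169 genes changed, 135 up and 34 down.

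From 4 to 8 weeks in NOD, MHC class II presentation rose in 7 of 12 members, with 0 falling (median 1.05, adjusted p = 7.80e-36, 10 over the list alone). Examples were H2-Eb1 (2850 to 8450 ± 785 CPM, 1.57 ± 0.17, adjusted p = 1.62e-06), Cd74 (1.24 ± 0.14) and H2-Ab1 (1.25 ± 0.16). Interferon-gamma response genes rose in 9 of 23 (median 1.55, adjusted p = 1.14e-32, 14 over the list alone), among them Gbp4 (2.74 ± 0.47) and Irf1 (1.72 ± 0.32). MHC class I presentation rose in 4 of 14 (median 0.73, adjusted p = 1.76e-18). Inflammatory cytokines and chemokines rose in 6 of 25 (median 0.96, or 1.01 with bounds, adjusted p = 5.71e-21), such as Ptgs2 (30.9 to 294 ± 48.9 CPM, 3.25 ± 0.39, adjusted p = 4.46e-06) and Nlrp3 (1.65). Type I interferon-stimulated genes were not called (median -0.03, adjusted p = 0.775). Complement rose in 1 of 14 (median 0.42, adjusted p = 1.82e-05). Immediate early and dissociation genes rose in 2 of 21 (median 0.80, adjusted p = 1.44e-17, adjusted p = 0.0517 with an estimated correlation). Glycolysis rose in 2 of 17 (median 0.18, adjusted p = 0.000122, adjusted p = 0.0614 with an estimated correlation). The glucose transporter gene Slc2a1 was one of them (1.53 ± 0.24, adjusted p = 0.000317). Monocyte (median 1.36, adjusted p = 5.72e-06), dendritic cell (median 1.55, adjusted p = 0.000792) and natural killer cell genes (8 measured, median 1.56, adjusted p = 0.0152) shifted up with 0 members passing. Endothelial and stromal genes did so too (median 0.34, adjusted p = 0.0162, adjusted p = 0.13 with an estimated correlation). Fitting these groups alone called 1228 genes, voom 1405, DESeq2 355 and a fit without the B6 4 week libraries 500. The count fell to 108, 110 and 103 without NOD 4 week replicates 1, 3 and 4, and to 112 and 104 without NOD 8 week replicates 2 and 3. Igf1 lost its call with the replicate block and in most single omissions, and Igf1, Il12b and Nlrp3 with no filter.

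Between 8 and 12 weeks in NOD (n = 4 and 3), Cxcl13 rose a further 9.34-fold (168 ± 40.9 to 1570 ± 707 CPM, 3.22 ± 0.31, adjusted p = 3.73e-07). It was the single gene called as rising in the fit of all libraries. Mmp12 fell 3.89-fold (578 ± 137 to 148 ± 20.0 CPM, -1.96 ± 0.24, adjusted p = 2.25e-05), and the endocytic receptor gene Lrp1 fell from 778 ± 178 to 308 ± 49.6 CPM (-1.34 ± 0.24, adjusted p = 0.00948). The chemokine gene Ccl9 fell from 105 to 35.8 CPM (-1.55 ± 0.26, adjusted p = 0.00421) and the deacetylase gene Hdac9 by -2.28 ± 0.40 (adjusted p = 0.00637), among 19 genes that fell. Lipid-associated and phagocytic genes shifted down with 0 members passing and 6 over the list alone (median -0.33, adjusted p = 0.000189). Inflammatory cytokines and chemokines did so with 1 (median -0.31, adjusted p = 3.56e-05), each list at adjusted p = 0.283 with an estimated correlation. Interferon-gamma response genes were not called (median 0.41, adjusted p = 0.0864), with a mean log2 CPM of 5.19 ± 0.09 at 8 weeks and 5.64 ± 0.16 at 12 weeks. T cell genes shifted up (median 1.5, adjusted p = 0.0078, adjusted p = 0.283 with an estimated correlation). Core macrophage identity genes shifted down by a median of -0.05 (adjusted p = 0.00789, adjusted p = 0.283 with an estimated correlation). That median was 0.06 under RLE and 0.05 under upper-quartile scaling. The fit of these groups alone called 728 genes (362 up, 366 down), voom 1846 (1293 up, 553 down), DESeq2 54 (14 up, 40 down), upper-quartile scaling 11 and a fit without the B6 4 week libraries 64. Without NOD 8 week replicates 1, 2 and 3 the count was 8, 13 and 9, and without NOD 12 week replicates 2 and 3 it was 5 and 4. Hdac9, Ccl9 and Lrp1 lost their call in single omissions, Lrp1 with no filter, and Hdac9 had no adjusted p in DESeq2.

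Over the whole span from 2 to 12 weeks in NOD (n = 4 and 3), Cxcl13 rose 605-fold (2.60 ± 0.823 to 1570 ± 707 CPM, 9.24 ± 0.41, adjusted p = 2.23e-16). Cxcl9 rose 361-fold (7.55 ± 5.53 to 2700 ± 628 CPM, 8.49 ± 1.05, adjusted p = 2.89e-05) and Ccl8 294-fold (0.604 to 178 ± 47.8 CPM, adjusted p = 4.75e-10). C3 rose from 30.2 ± 7.55 to 1410 ± 211 CPM (5.55 ± 0.42, adjusted p = 4.38e-10). Sparc fell 22.0-fold to 18.5 ± 0.795 CPM (-4.46 ± 0.43, adjusted p = 1.56e-08). Cd36 fell 16.2-fold (108 ± 15.3 to 6.66 ± 1.55 CPM, -4.02 ± 0.32, adjusted p = 2.60e-10) and Hpgd, which encodes a prostaglandin-degrading enzyme, 13.5-fold (-3.75 ± 0.40, adjusted p = 1.17e-07). The adhesion receptor gene Adgrl2 (-3.83 ± 0.56), the basement membrane gene Nid2 (-4.72 ± 0.84) and Trem2 (164 to 50.1 CPM, -1.71 ± 0.25) fell too. Rises of Ly6a (8.75 ± 1.30, adjusted p = 3.54e-05) and Serpina3g (8.06 ± 0.94) are uncertain, since both have close copies. In total 599 genes changed, 352 up and 247 down (420 and 170 with upper-quartile scaling).

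Over the same span in NOD, MHC class II presentation rose in 10 of 12 members, with 0 falling (median 1.84, adjusted p = 1.98e-29). H2-Ab1 (chromosome 17, 34257689 to 34269419) rose from 1330 ± 199 to 9100 ± 680 CPM (2.77 ± 0.18, adjusted p = 2.30e-12). H2-Eb1 rose from 1180 ± 264 to 9600 ± 963 CPM (3.02 ± 0.19, adjusted p = 1.89e-12) and Ciita from 48.5 to 226 ± 20.8 CPM (2.22 ± 0.25, adjusted p = 2.66e-07). Interferon-gamma response genes rose in 15 of 23 (median 2.54, adjusted p = 7.73e-27, 20 over the list alone), with Gbp4 (3.5 ± 0.5) beside Cxcl9. MHC class I presentation rose in 10 of 14 (median 1.44, adjusted p = 4.45e-20), H2-K1 from 276 ± 27.7 to 1250 ± 183 CPM (2.18 ± 0.17, adjusted p = 9.45e-11). Complement had 6 rising and 1 falling (median 1.32, adjusted p = 1.44e-05). Type I interferon-stimulated genes rose in 4 of 26 (median 0.72, adjusted p = 0.000105, adjusted p = 0.15 with an estimated correlation). Inflammatory cytokines and chemokines rose in 6 with 3 falling (median 0.51, adjusted p = 9.84e-05, adjusted p = 0.199 with an estimated correlation), and glycolysis genes in 5 of 17 (median 0.44, adjusted p = 0.00815, adjusted p = 0.199 with an estimated correlation). Cell cycle genes shifted down with 0 of 32 passing (median -0.82, adjusted p = 1.94e-06, adjusted p = 0.0679 with an estimated correlation). Lipid-associated and phagocytic genes had 3 rising and 7 falling without a call for the list (median 0.09, adjusted p = 0.0971). Also without a call were alternatively activated or perivascular macrophage markers, with 2 rising and 3 falling of 18 (median 0.40, adjusted p = 0.528).

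Genes of other immune cells moved with these groups in NOD from 2 to 12 weeks. Natural killer cell genes had a median of 2.80 (2.93 with bounds, adjusted p = 0.00277), monocyte genes 1.96 (adjusted p = 0.00103) and T cell genes 1.80 (adjusted p = 0.000975), with 1, 0 and 0 members passing. The T cell gene Cd3e stood at 0 CPM at 2 weeks and 2.42 ± 0.988 at 12 weeks (adjusted p = 0.0695). Dendritic cell genes rose in 3 members and fell in 1 of 15 (median 1.76, adjusted p = 0.00815, adjusted p = 0.0679 with an estimated correlation). Clec9a, a marker of conventional dendritic cells, rose (1.03 to 117 ± 37.3 CPM, 6.86 ± 1.21, adjusted p = 0.000883), and Siglech fell (-2.74). Islet endocrine genes were not called (median 0.69, adjusted p = 0.198). Neither were duct cell genes (median 0.83, adjusted p = 0.363), neutrophil genes (median -0.34, adjusted p = 0.61), erythroid genes (median -0.32, adjusted p = 0.61) or genes of B cells and plasma cells, of which 2 of 10 rose (median 1.68, adjusted p = 0.17). Camera with the preset correlation called neither these 4 lists nor the acinar and alternatively activated lists in any comparison, while fry called acinar genes in 2 and neutrophil, erythroid and B cell genes in 1 each. Fitting the groups alone called 1701 genes, voom 3458, DESeq2 995 and a fit without the B6 4 week libraries 1641. The count was 373 without NOD 12 week replicate 1 and 351 without NOD 12 week replicate 3.

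In B6, macrophages at 4 weeks (n = 4) held more Cd74 (1.85 ± 0.16, adjusted p = 1.23e-08) and H2-Ab1 (1.76 ± 0.18) than at 2 weeks (n = 3). The lysozyme gene Lyz2 (1.76 ± 0.26) and Apoe (1.17 ± 0.16) rose too, and the efferocytosis receptor gene Mertk fell (-1.91). The ubiquitin ligase gene Trim32 rose by 4.20 ± 0.86 (adjusted p = 0.00385) and Nadsyn1, of NAD synthesis, from 2.05 ± 1.40 to 18.0 ± 4.06 CPM (adjusted p = 0.0195). Capn12, a calpain gene, fell by a ratio of 360 (64.5 to 14200). Gas8 and Hpca had 0 counts at 4 weeks (falls of at least 82.5-fold and 60.8-fold). MHC class II presentation had 6 of 12 rising and 1 falling (median 0.89, adjusted p = 5.72e-11), and core macrophage identity 8 rising and 2 falling of 18 (median 0.41, adjusted p = 5.83e-07). Lipid-associated and phagocytic genes had 8 rising and 1 falling (median 0.45, adjusted p = 4.84e-06, adjusted p = 0.246 with an estimated correlation). Cell cycle genes had 5 falling, Top2a included (-1.96, list median -0.59, adjusted p = 0.00141, adjusted p = 0.413 with an estimated correlation). Immediate early and dissociation genes had 4 rising (median 0.58, adjusted p = 3.09e-07, adjusted p = 0.423 with an estimated correlation). In total 1451 genes changed, 603 up and 848 down, but 569 up and 489 down with the stricter filter and 238 up and 1014 down with upper-quartile scaling. A fit of the 2 groups alone called 5 genes and voom 52, all of them up, and DESeq2 2686, and 9 of the 11 genes named here, all but Cd74 and H2-Ab1, were not called in that fit of 2 groups. Single omissions gave 714, 664 and 759 genes (B6 2 week replicates 1, 2 and 3) and 2331 and 2363 (B6 4 week replicates 1 and 4).

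From 4 to 12 weeks in B6 (n = 4 each), the macrophage transcription factor gene Spi1 fell (-1.72 ± 0.17, adjusted p = 2.23e-08), as did the complement gene C1qc (-1.29 ± 0.11), the growth factor gene Tgfb1 (-1.40 ± 0.12) and Cd74 (-1.05 ± 0.14). The mitotic regulator gene Cdc20 fell by -4.85 ± 1.02 (adjusted p = 0.00138) and the growth factor gene Igf2 from 38.9 ± 29.0 to 1.33 ± 2.23 CPM (-4.80 ± 0.89, adjusted p = 0.000365). Lrrn3 (at least 71.3-fold), Tgm6 (at least 65.2-fold) and Gas8 (at least 62.4-fold) rose from 0 counts. The embryonic globin gene Hba-x, of a family of close copies and thus uncertain, fell by a ratio of 427 (118 to 3530). Core macrophage identity had 10 of 18 members falling and 1 rising (median -0.41, adjusted p = 6.40e-09). MHC class I presentation had 7 of 14 falling and 1 rising (median -0.69, adjusted p = 9.27e-05, adjusted p = 0.257 with an estimated correlation). MHC class II presentation had 4 falling and 2 rising (median -0.53 but mean 0.08, camera direction down, adjusted p = 0.0452, adjusted p = 0.671 with an estimated correlation). Complement had 4 falling (median -0.39, or -0.54 with bounds, but mean 0.03, camera direction down, adjusted p = 0.00297, adjusted p = 0.0749 with an estimated correlation). Lipid-associated and phagocytic genes had 6 falling and 1 rising (median -0.38, adjusted p = 5.25e-05, adjusted p = 0.257 with an estimated correlation). Islet endocrine genes had 5 of 17 falling and 1 rising (median -0.84, adjusted p = 0.0103, adjusted p = 0.576 with an estimated correlation). Of 3720 genes called, 2043 rose and 1677 fell, but 1076 and 1425 with the stricter filter, 71 and 321 in the groups alone and 34 and 371 with voom. A fit of the 2 groups alone called 392, 390 of them among the 3720, and voom called 405, without Lrrn3, Tgm6, Gas8 and Cdc20. Upper-quartile scaling moved the median of all genes from 0.06 to 0.30 and the share of rising genes from 54.9% to 73.9%.

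Between 2 and 12 weeks in B6 (n = 3 and 4), Ccr2 rose 12.9-fold (6.49 ± 1.83 to 84.0 ± 23.6 CPM, 3.69 ± 0.42, adjusted p = 2.74e-06). Wfdc17, a secreted whey acidic protein family gene, rose 23.8-fold (3.35 ± 0.423 to 80.0 ± 7.85 CPM, adjusted p = 5.38e-05) and the integrin gene Itgb8 15.8-fold (5.34 ± 3.62 to 84.8 ± 18.1 CPM, adjusted p = 0.00184). The magnesium transporter gene Slc41a2 (4.33 ± 0.67, adjusted p = 0.000202) and Mmp12 (308 to 855 CPM, 1.47 ± 0.23, adjusted p = 0.000208) rose too. Plk1, a mitotic kinase gene, fell 11.6-fold (20.7 ± 5.44 to 1.76 ± 1.63 CPM, adjusted p = 0.00595) and Mki67 from 372 ± 130 to 101 ± 32.9 CPM (-1.88 ± 0.29, adjusted p = 0.000208). In all 7 of 32 cell cycle genes fell and 0 rose (median -1.37, adjusted p = 2.65e-14, 18 over the list alone). Gcg, the glucagon gene, fell from 275 ± 188 to 10.3 ± 14.7 CPM (-4.75 ± 0.99, adjusted p = 0.0125), a call lost with voom, the islet covariate, the groups alone (adjusted p = 0.0817 to 0.127) or B6 2 week replicate 1 left out. Islet endocrine genes had a median of -1.23 (1 of 17 falling, adjusted p = 2.31e-07, adjusted p = 0.0646 with an estimated correlation). MHC class II presentation rose in 5 of 12 (median 0.64, adjusted p = 7.67e-09, adjusted p = 0.0646 with an estimated correlation). H2-Aa was one of them (2830 to 8350 CPM, 1.56 ± 0.18, adjusted p = 2.95e-06). Interferon-gamma response genes had 2 rising and 2 falling and were not called (median -0.64, adjusted p = 0.404). Cxcl10 was among those falling (91.8 to 24.2 CPM, -1.92 ± 0.39, adjusted p = 0.00427), a call lost with voom, the islet covariate and without B6 2 week replicate 2. In total 392 genes changed, 151 up and 241 down, but 193 up and 184 down with upper-quartile scaling and 523 up and 442 down with DESeq2. DESeq2 called 965 and a fit without the B6 4 week libraries 1807, and the islet covariate left 231. Single omissions gave 250, 196 and 185 genes (B6 2 week replicates 1, 2 and 3) and 244, 246 and 233 (B6 12 week replicates 1, 2 and 3).

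Tests of the strain-by-age interaction gave the genes whose change differed between strains. For 2 to 12 weeks these were 329, 205 with a larger and 124 with a smaller log2 change in NOD. C3 changed more in NOD (difference 5.38 ± 0.55, adjusted p = 4.12e-07), as did H2-K1 (2.22 ± 0.23, adjusted p = 2.25e-07) and Gbp4 (5.24 ± 0.69, adjusted p = 1.19e-05). Iigp1 (10.78 ± 1.38), Cd74 (1.45 ± 0.21, adjusted p = 4.33e-05) and, uncertain for their close copies, Ly6a (12.04 ± 1.66) and Serpina3g (10.77 ± 1.22, adjusted p = 1.05e-06) did too. Without B6 2 week replicate 2, where Ly6a stood at 24.2 CPM against 0.331 and 0.456, the differences were 7.77 (Iigp1), 7.67 (Ly6a) and 8 (Serpina3g). Genes with a more negative change in NOD included Mmp12 (-3.74 ± 0.33, adjusted p = 9.24e-09), Cd36 (-4.25 ± 0.41, adjusted p = 6.18e-08) and Siglech (-4.17 ± 0.46, adjusted p = 7.18e-07). Hpgd (-4.36 ± 0.52), Ccr2 (-3.73 ± 0.54, adjusted p = 5.24e-05) and Trem2 (-2.27 ± 0.35) were others. By list, 13 of 23 interferon-gamma response genes changed more in NOD and 0 less (median difference 3.11, adjusted p = 6.03e-22). So did 10 of 14 genes of MHC class I presentation (1.71, adjusted p = 1.68e-19) and 6 of 12 of MHC class II presentation (1.42, adjusted p = 7.70e-12). Larger changes were also found in 4 complement genes, with 1 the other way (1.90, adjusted p = 3.93e-07), and in 3 of 26 type I interferon-stimulated genes (1.11, adjusted p = 6.15e-05, adjusted p = 0.144 with an estimated correlation). Islet endocrine (1.96, adjusted p = 3.01e-07) and T cell genes (2.17, adjusted p = 0.00102) also differed, with 0 members passing. The groups alone gave 705 genes, voom 790, DESeq2 661, a fit without the B6 4 week libraries 1191 and the islet covariate 120. Cd74 lost its call with voom. The count was 205 without NOD 12 week replicate 3 and 187 without B6 2 week replicate 2.

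For the change from 4 to 12 weeks, 874 genes differed between strains, 489 with a larger (more positive) and 385 with a smaller (more negative) change in NOD. Upper-quartile scaling gave 360 larger and 527 smaller, and DESeq2 915 and 991. More positive changes in NOD included Cd74 (2.13 ± 0.20, adjusted p = 5.12e-08), Ptgs2 (4.01 ± 0.54) and Cxcl9 (4.30 ± 1.14, adjusted p = 0.0361). The call of Cxcl9 was lost with voom, no filter, the replicate block, the groups alone (adjusted p = 0.0602 to 0.425) and most single omissions. Mmp12 was among those with a more negative change (-3.01 ± 0.31). Called lists included MHC class I presentation (9 of 14 larger, median 1.69, adjusted p = 7.77e-16) and MHC class II presentation (7 larger and 1 smaller of 12, median 1.88, adjusted p = 1.96e-15). Interferon-gamma response (6 of 23 larger, median 1.56, adjusted p = 3.76e-11), complement (4 of 14, median 1.08, or 1.22 with bounds, adjusted p = 1.70e-07) and core macrophage identity genes (5 larger and 1 smaller of 18, median 0.49, adjusted p = 1.65e-05) were called. The groups alone gave 292 genes, voom 315 and DESeq2 1906. Omission of NOD 12 week replicates 1, 2 and 3 gave 444, 466 and 448, and of B6 4 week replicates 1, 3 and 4 gave 1460, 1589 and 1706.

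For 2 to 4 weeks, 176 genes differed between strains, 129 with a larger (more positive) and 47 with a smaller (more negative) change in NOD (189 and 19 with upper-quartile scaling). Smaller changes included Sparc (-3.83 ± 0.51, adjusted p = 0.000449), Apoe (-1.06, adjusted p = 0.0171) and Cd36 (-1.53, adjusted p = 0.0401). Interferon-gamma response genes had 4 of 23 larger (median 1.32, adjusted p = 0.0025) and islet endocrine genes 1 of 17 (median 2.09, adjusted p = 0.000845). MHC class II presentation had 1 of 12 larger (median -0.44, mean 0.16, camera direction down, adjusted p = 0.00139), each list at adjusted p = 0.446 with an estimated correlation. The groups alone gave 2 genes, voom 3, DESeq2 923 and the islet covariate 20. Apoe and Cd36 lost their call in the groups alone, with upper-quartile scaling, the islet covariate and single omissions, Apoe also with no filter and Cd36 with voom and the replicate block. All 15 single omissions moved the count by over 1.5 times, from 39 without NOD 2 week replicate 3 to 651 without B6 4 week replicate 4.

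The changes from 2 to 12 weeks in the 2 strains correlated weakly across genes (Pearson r = 0.121, Spearman 0.146), where genes are not independent replicates. Of 352 genes that rose in NOD, 42 also rose in B6 and 194 had the same direction of change there, and of 247 that fell, 36 fell in B6 and 173 had the same direction. By independent calls 2.7 and 3.02 shared genes would be found, and 19 genes were called in opposite directions. The Pearson value turned to -0.077 with the islet covariate, and ranged from 0.021 without B6 12 week replicate 1 to 0.172 without B6 2 week replicate 1.

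**Figure D1:**
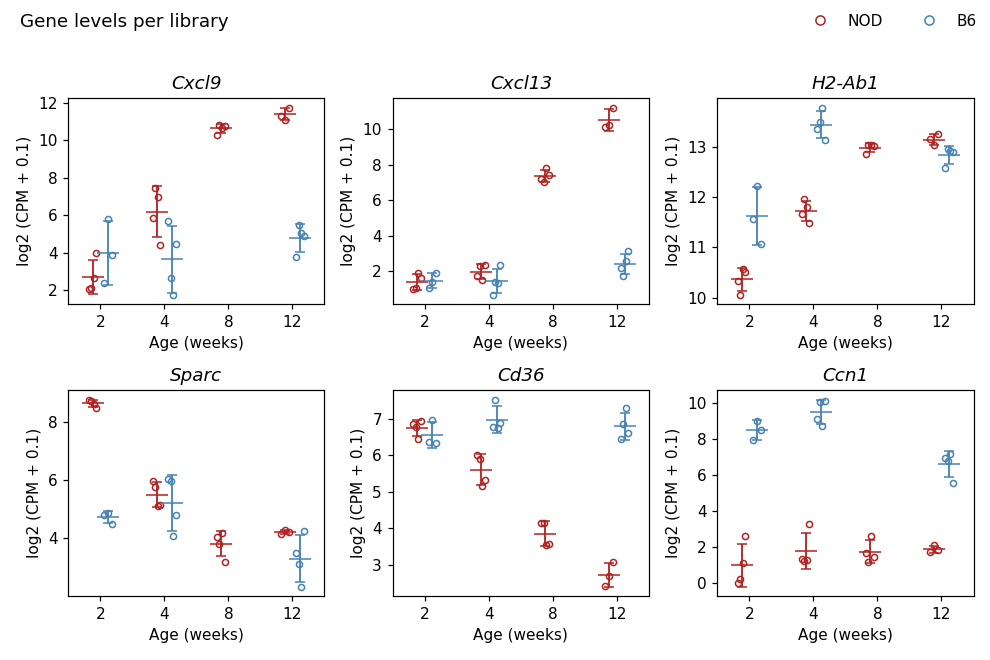
Level of 6 genes per library as log2(CPM + 0.1) against age in weeks, NOD in red and B6 in blue, with the mean and SD of each group as point and bar. In NOD at 12 weeks Cxcl9 reached 2700 ± 628 CPM, Cxcl13 1570 ± 707, H2-Ab1 9100 ± 680, Sparc 18.5 ± 0.795 and Cd36 6.66 ± 1.55, and Ccn1 stayed below B6 at each age.

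**Figure D2:**
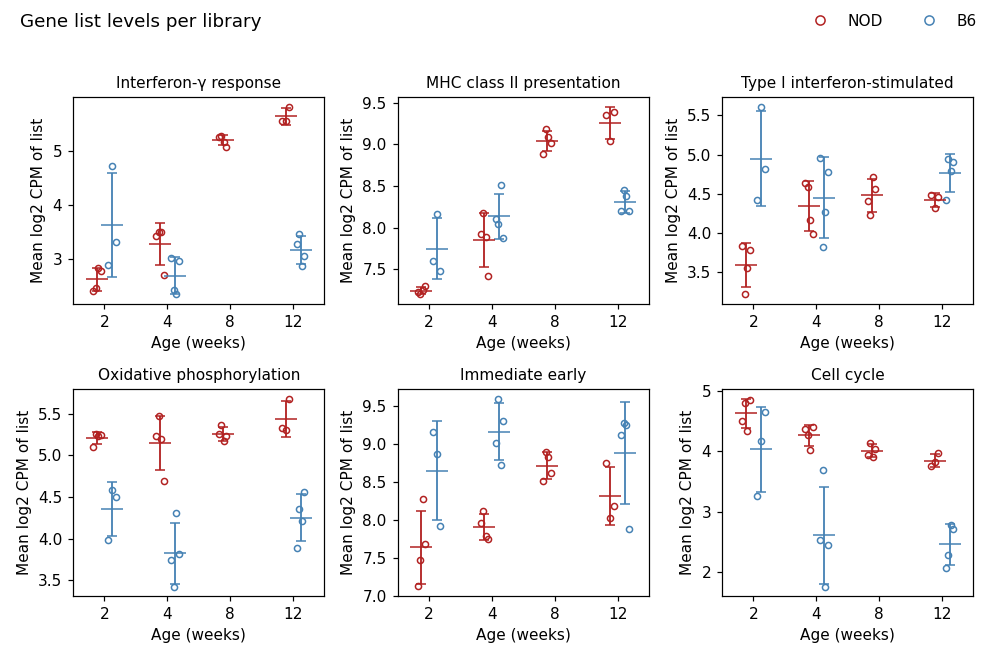
Mean log2 CPM over the members of 6 gene lists per library against age in weeks, NOD in red and B6 in blue, with group mean and SD as point and bar. In NOD the interferon-gamma response mean was 2.62 at 2 weeks and 5.64 at 12 weeks, the MHC class II mean 7.24 and 9.26, and the oxidative phosphorylation mean lay above B6 at each age.

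**Figure D3:**
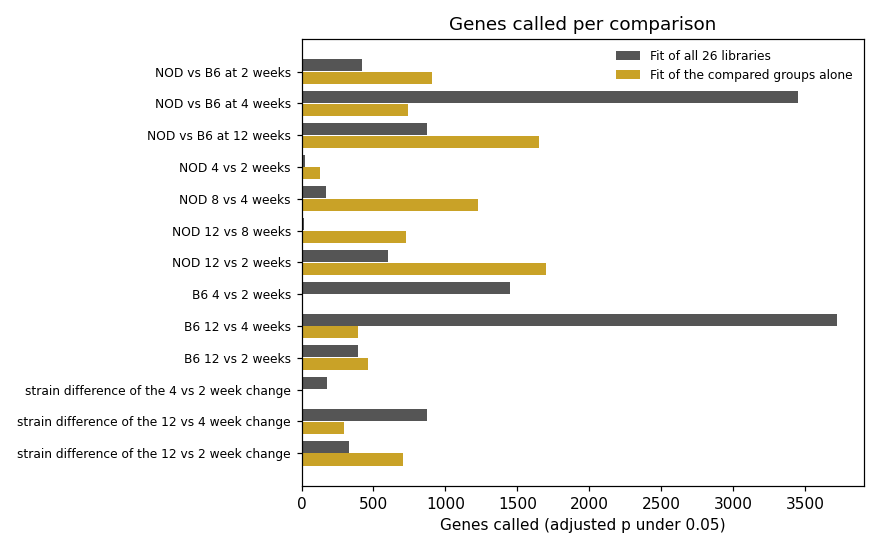
Number of genes called at adjusted p under 0.05 (horizontal axis) for each comparison (vertical axis), with the fit of all 26 libraries in grey and the fit of the compared groups alone in gold. The fit of all libraries called more genes in comparisons with the B6 4 week group, 3720 against 392 for B6 12 against 4 weeks, and fewer in most others, such as 599 against 1701 for NOD 12 against 2 weeks.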

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

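The tests of unequal spread and depth in the B6 4 week libraries were chosen after the results were seen. So were the islet covariate for the interferon-gamma list and the fits without those libraries. The other tests and the 3 rules for picking values were set before. Transcript loss, length and GC content were tested on patterns seen in results.

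The 3 comparisons of 2 groups that included the B6 4 week libraries called the most genes, 1451, 3450 and 3720. Counts simulated with no change between groups, but with each group's own spread, gave 581 calls in NOD against B6 at 4 weeks, 558 in B6 4 against 2 weeks and 785 in B6 12 against 4 weeks, 67 and 17 in the interactions of 4 with 2 and 12 with 4 weeks, and 0 in the comparisons without this group. Only 5 genes were called in B6 4 against 2 weeks when these groups alone were fitted, against 1451, so unequal spread likely adds to these counts. Loss of transcripts at random in single libraries is consistent with the 28 of 5319 abundant genes that had a 0 count in this group, 96.4% of them in exactly 1 of the 4 libraries, but so few genes do not show how much of these counts it explains. Lower depth is argued against, since the lowest total of these libraries, 9.75 in units of 1e+06 counts, lies above the highest of the other B6 libraries, 8.42, and a difference due to the age of the mice stays open and untested.

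The interferon-gamma response list rose in NOD from 2 to 12 weeks, with a median of 2.59 in limma coefficients of log2 CPM (2.54 in edgeR fold changes). With T, natural killer and B cell levels as a covariate the median was 2.11 (quartiles 1.37 to 3.99, camera adjusted p = 4.41e-15), and with islet endocrine and acinar levels 2.41 (1.34 to 3.63, adjusted p = 2.15e-27), which argues against RNA of those cells as the whole cause. With monocyte and dendritic cell levels the median was 0.75 (0.16 to 2.1, adjusted p = 0.000176), so a change within macrophages and RNA of monocytes or dendritic cells cannot be told apart. These lists shifted up with age in the same NOD libraries, with 0 monocyte genes passing (median 1.96, adjusted p = 0.0109 with an estimated correlation) and 3 dendritic cell genes rising and 1 falling (1.76, adjusted p = 0.0679 with it). A change with age or disease in NOD stays open too.

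By camera with a preset correlation, oxidative phosphorylation genes were higher and immediate early genes lower in NOD at all 3 ages. With an estimated correlation, only oxidative phosphorylation at 12 weeks kept its call (adjusted p = 0.00936, against 0.0601 and 0.22 at 2 and 4 weeks), and the immediate early list had adjusted p = 0.188 to 0.266. Transcript length and GC content are argued against as the whole cause: among 10000 random lists matched on exon length, GC content and expression, the oxidative phosphorylation median lay at the percentile 99.97 or above at each age, and the immediate early median at the percentile 0. A difference due to strain stays open, as does one in handling, since the labels name no batch, and neither was tested.

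Other splits test whether labels can be swapped. With the B6 4 week group, a top count does not exclude unequal spread. Counts in NOD against B6 at 2, 4 and 12 weeks were 421 (highest other 81), 3450 (357) and 875 (382). The labelled split gave the most genes there, 1 of 35. So it did in NOD 4 against 2 weeks (27, 1), 8 against 4 weeks (169, 0), 12 against 8 weeks (20, 1) and 12 against 2 weeks (599, 121), and in B6 12 against 4 weeks (3720, 947) and 12 against 2 weeks (392, 200). For the interactions of 12 with 2 weeks (329, 250) and 12 with 4 weeks (874, 948), 1 and 2 of 60 splits gave as many. Chance cannot be excluded for B6 4 against 2 weeks (1451, 2332), where 4 of 35 splits gave as many. Nor can it for the interaction of 4 with 2 weeks (176, 1556), where 7 of 60 did. A split that swaps strains at 1 age can carry the strain difference into an interaction, so these shares of 60 do not measure chance alone.

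Single libraries stood apart from the other 3 of their group by Dixon's test in 20 of 194 groups tested over 39 measures, where chance gives about 1 in 20. The share of counts at the ribosomal RNA locus was 12.8% in B6 12 week replicate 4, and the share of Plekhh2 was 4.685% in NOD 2 week replicate 3 and 15.3% in B6 12 week replicate 2. Mean log2 CPM of lists stood apart for interferon-gamma response (2.69) and growth factors and matrix remodelling (3.85) in NOD 4 week replicate 4, core macrophage identity in B6 12 week replicate 1 (8.61) and lipid-associated genes in NOD 8 week replicate 2 (7.17). Others were immediate early genes in B6 12 week replicate 4 (7.87), oxidative phosphorylation in NOD 2 week replicate 1 (5.1) and cholesterol biosynthesis in NOD 2 week replicate 3 (2.96). Of other cells, natural killer genes stood apart in B6 12 week replicate 2 (-0.97), endothelial and stromal genes in NOD 8 week replicate 3 (1.63), and duct genes in NOD 4 week replicate 1 (0) and B6 12 week replicate 3 (-0.93). Prss2 was at 2.44, 3.28 and 5.79 CPM in NOD 2 week replicate 3, NOD 8 week replicate 1 and B6 4 week replicate 3, and Cd3e at 3.44, 9.86 and 1.8 CPM in NOD 8 week replicate 4, B6 4 week replicate 1 and B6 12 week replicate 4.

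The change with age differed between strains by the interaction test for 176 genes (4 against 2 weeks), 874 (12 against 4 weeks) and 329 (12 against 2 weeks). For 12 against 4 weeks the lists whose call held with an estimated correlation had median differences of 1.56 (interferon-gamma response), 1.88 (MHC class II), 1.69 (MHC class I), 0.49 (core macrophage identity) and 1.08 (complement). For 12 against 2 weeks these were 3.11 (interferon-gamma response), 1.42 (MHC class II), 1.71 (MHC class I), 1.9 (complement), 1.96 (islet endocrine) and 2.17 (T cells). The named genes of that comparison were Ly6a (12.04), Iigp1 (10.78), Serpina3g (10.77), Sema7a (9.73) and Ly6i (9.11), and St6galnac1 (-7.36), Atp2b4 (-4.39), Hpgd (-4.36), Cd36 (-4.25) and Siglech (-4.17). Without B6 2 week replicate 2 the differences of Ly6a, Iigp1, Serpina3g, Sema7a and Ly6i were 7.67, 7.77, 8, 7.45 and 7.42, and Sema7a was no longer called, nor without NOD 2 week replicate 2 (adjusted p = 0.0513). Sema7a and Ly6i also lost their call with the islet covariate. The value of St6galnac1 rests on 0 counts in B6 at 2 weeks, so its size is not exact, and its call was lost in 6 single omissions (adjusted p = 0.0591 to 0.293) and with voom, the replicate block and the islet covariate. Ly6a, Ly6i and Serpina3g have close copies and are uncertain.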

How the results depend on the processing

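Alternatives changed 1 choice at a time, except that fits with fewer groups or without 1 library also changed the genes tested and the scaling, and limma-voom with sample weights changed the method and the weights together. A count was kept when it stayed within 1.5 times its value in the reported fit. Of 290 results for genes of the naming rule, all kept direction, and 281 stayed on their side of the threshold with DESeq2, 234 of 279 in fits of only the groups compared, 252 with the islet covariate, 276 with no filter and 269 with the replicate block. With limma-voom and sample weights 65 lost their call and 2 gained one. In fits of only the groups compared, 15 of the 17 such genes in B6 4 against 2 weeks and 12 of 13 in the interaction of 4 with 2 weeks lost their call. The islet covariate could lower real changes too. The cause was not tested for any change below unless stated. The pseudocount alternative was not run because the file holds counts. A gene that DESeq2 left without an adjusted p stayed without a call.

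With DESeq2, NOD against B6 gave 1147 genes at 2 weeks and 1418 at 12 weeks. NOD gave 105 (4 against 2 weeks), 355 (8 against 4), 54 (12 against 8) and 995 (12 against 2), B6 2686 (4 against 2) and 965 (12 against 2), the interactions 923 (4 against 2), 1906 (12 against 4) and 661 (12 against 2), and 287 genes were shared by all ages. Limma-voom with sample weights gave 1021, 706 and 1969 between strains at 2, 4 and 12 weeks, 173, 1405, 1846 and 3458 in NOD (4 against 2, 8 against 4, 12 against 8, 12 against 2), 52 and 405 in B6 (4 against 2, 12 against 4) and 3, 315 and 790 in the interactions (4 against 2, 12 against 4, 12 against 2). Fits of only the groups compared gave, in the same order, 906, 742 and 1651, then 128, 1228, 728 and 1701, then 5 and 392, and 2, 292 and 705.

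Without the B6 4 week libraries, an alternative chosen after seeing the data, the counts were 1880 and 2211 between strains (2 and 12 weeks), 114, 500, 64 and 1641 in NOD, 1807 in B6 (12 against 2) and 1191 in the interaction (12 against 2). With the islet covariate they were 1568 and 392 between strains (4 and 12 weeks), 603 and 231 in B6 (4 against 2, 12 against 2), 20 and 120 in the interactions (4 against 2, 12 against 2) and 100 shared by all ages. The correlation of the 12 against 2 week changes reversed from 0.121 to -0.077, the islet endocrine list was called in 2 of 13 comparisons and the acinar list in 1. Upper-quartile factors gave 11 genes in NOD 12 against 8 weeks, a log2 change of at least 1 gave 13 there and 248 in B6 12 against 2 weeks, and no filter gave 114 in the interaction of 4 with 2 weeks.

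The replicate block, which pairs libraries by a number that the labels share and nothing else, gave 51 genes in the interaction of 4 with 2 weeks and changed no other call of a count. Correlations of libraries with the same number ran from -0.111 to 0.062, and no set of pairs was all over 0.1.

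Scaling moved the share of genes called higher by more than 10 points in 9 comparisons. Upper-quartile factors took it from 42% to 24.1% (RLE 30.5%) and 53.5% to 41.2% between strains at 2 and 12 weeks, 5% to 18.2% and 58.8% to 71.2% in NOD (12 against 8, 12 against 2), 41.6% to 19%, 54.9% to 73.9% and 38.5% to 51.2% in B6 (4 against 2, 12 against 4, 12 against 2) and 73.3% to 90.9% and 55.9% to 40.6% in the interactions (4 against 2, 12 against 4). The median of all genes moved with it, in B6 4 against 2 weeks from 0.01 to -0.21 and in B6 12 against 4 weeks from 0.06 to 0.3. Of 128 called list medians 4 changed sign: core macrophage identity in NOD 12 against 8 weeks (-0.05 to 0.06 and 0.05), inflammatory genes in B6 4 against 2 weeks (0.15 to -0.06), immediate early genes in B6 12 against 4 weeks (-0.25 to 0.06) and lipid-associated genes in the interaction of 4 with 2 weeks (-0.21 to 0.03).

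With an estimated correlation between members, 42 of 128 list tests stayed past the threshold, and with fry 80. Lists were then called with an estimated correlation in 2 (type I interferon), 5 (interferon-gamma), 6 (MHC class II), 6 (MHC class I), 1 (inflammatory), 3 (core macrophage), 0 (lipid-associated), 2 (cell cycle), 0 (growth factors), 0 (immediate early), 0 (glycolysis), 1 (oxidative phosphorylation), 1 (cholesterol), 2 (islet endocrine), 2 (T cells), 1 (dendritic cells) and 0 (endothelial) of 13 comparisons. With fry they were called in 6 (MHC class I), 4 (inflammatory), 1 (lipid-associated), 5 (cell cycle), 0 (growth factors), 2 (immediate early), 5 (glycolysis), 2 (acinar), 1 (B cells), 7 (dendritic cells), 1 (neutrophils), 4 (natural killer), 4 (endothelial) and 1 (erythroid). The covariate kept 113 of 128, the block 126 and fits without the B6 4 week libraries 80 of 84.

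Leaving out 1 library, the counts ran between strains from 239 to 326 (2 weeks), 2333 to 4525 (4 weeks) and 529 to 874 (12 weeks), in NOD from 16 to 24 (4 against 2), 103 to 137 (8 against 4), 4 to 20 (12 against 8) and 351 to 477 (12 against 2), in B6 from 664 to 2363 (4 against 2), 2617 to 4647 (12 against 4) and 185 to 433 (12 against 2), and in the interactions from 39 to 651 (4 against 2), 444 to 1706 (12 against 4) and 187 to 325 (12 against 2). Genes shared by all ages ran from 114 to 164 and the correlation from 0.021 to 0.172 (jackknife SE 0.118). The cause of these falls and rises was not tested.

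Libraries whose omission moved a count more than 1.5 times were, between strains, NOD 2 week replicate 2 (280) and B6 2 week replicates 1 (250) and 2 (239) at 2 weeks, and NOD 12 week replicate 3 (529) at 12 weeks. In NOD they were, for 4 against 2 weeks, NOD 2 week replicate 2 (17) and 4 week replicate 3 (16), for 8 against 4 weeks, NOD 4 week replicates 1 (108), 3 (110) and 4 (103) and 8 week replicates 2 (112) and 3 (104), for 12 against 8 weeks, NOD 8 week replicates 1 (8), 2 (13) and 3 (9) and 12 week replicates 2 (5) and 3 (4), and for 12 against 2 weeks, NOD 12 week replicates 1 (373) and 3 (351). In B6 they were, for 4 against 2 weeks, B6 2 week replicates 1 (714), 2 (664) and 3 (759) and 4 week replicates 1 (2331) and 4 (2363), and for 12 against 2 weeks, B6 2 week replicates 1 (250), 2 (196) and 3 (185) and 12 week replicates 1 (244), 2 (246) and 3 (233). In the interaction of 4 with 2 weeks they were NOD 2 week replicates 1 (59), 2 (57), 3 (39) and 4 (61), NOD 4 week replicates 1 (60), 2 (78), 3 (61) and 4 (109), B6 2 week replicates 1 (113), 2 (65) and 3 (76) and B6 4 week replicates 1 (640), 2 (356), 3 (569) and 4 (651). For 12 with 4 weeks they were NOD 12 week replicates 1 (444), 2 (466) and 3 (448) and B6 4 week replicates 1 (1460), 3 (1589) and 4 (1706), and for 12 with 2 weeks NOD 12 week replicate 3 (205) and B6 2 week replicate 2 (187).

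Depth limits low genes: with totals of 4.96e+06 to 1.386e+07 counts, a gene at 1 CPM had about 5 to 14 counts in a library, and fold changes between 2 groups from 0 counts were given only as bounds.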

Other observations

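Several receptor genes differed between the strains at more than 1 age. The scavenger receptor gene Msr1 was higher in NOD at 2 weeks (33.3 ± 3.71 against 5.7 ± 1.77 CPM, log2 fold change 2.54 ± 0.56, edgeR adjusted p = 0.00748), 4 weeks (46 ± 6.52 against 2.75 ± 2.97 CPM, 4.04 ± 0.53, adjusted p = 3.49e-06) and 12 weeks (adjusted p = 0.00236). Fcgr1 was also higher at 2 weeks (680 ± 83.8 against 254 ± 27.3 CPM, adjusted p = 2.75e-06), 4 weeks (589 ± 74.1 against 255 ± 38.5 CPM, adjusted p = 3.43e-06) and 12 weeks (767 ± 166 against 128 ± 30 CPM, adjusted p = 9.29e-12). Stab1, an endocytic scavenger receptor gene, was lower in NOD by -1.02, -1.51 and -0.94 at 2, 4 and 12 weeks, and the tetraspanin gene Cd81 by -1.07, -1.29 and -0.81, all with adjusted p under 0.05. Msr1 lost its call at 2 weeks without B6 2 week replicate 2 (adjusted p = 0.0794) and at 4 weeks with voom (0.0791), and Stab1 at 2 weeks without B6 2 week replicate 1 (0.102) and at 12 weeks with the islet covariate (0.352).

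The membrane metalloprotease gene Mmp14 rose from 126 ± 3.65 CPM at 2 weeks to 351 ± 66.5 at 12 weeks (1.48 ± 0.19, edgeR adjusted p = 4.57e-06) and changed more than in B6 (interaction 2.1 ± 0.27, adjusted p = 8.68e-06). The progranulin gene Grn also had a positive interaction (1.4 ± 0.21, adjusted p = 6.90e-05) and fell in B6 from 1460 ± 138 to 796 ± 113 CPM (-0.87 ± 0.15, adjusted p = 0.000674). The interleukin-4 receptor gene Il4ra rose in NOD from 231 ± 25 to 437 ± 41.4 CPM (0.92 ± 0.18, adjusted p = 0.0017). Ccr2 rose in B6 and had a smaller change in NOD, with 47.1 ± 17.8, 51.2 ± 7.24, 68.2 ± 14.4 and 45.9 ± 9.94 CPM at 2, 4, 8 and 12 weeks.

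A hypothesis was that the 164 genes called in the same direction at all 3 ages lie close together along the genome, as they would where stretches of chromosome differ between the strains. Of these genes, 57 (34.8%) had another of them starting within 1 Mb, against a median of 34 (95% range 21 to 48) in 10000 random sets of tested genes of the same size, and at most 69. Clustering along the genome is thus consistent with these values, while families of neighbouring copies, such as Ifi202b, Ifi206, Ifi209 and Ifi213 on chromosome 1, could give the same result and were not separated from it. Strain variants against the reference were not tested.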
